A study of Homo sapiens with 12 samples.

How the data were processed

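HepG2 is a human hepatocellular carcinoma cell line. Per the labels' protocols, it was infected with lentivirus made in HEK293T cells, carrying an shRNA against SETD2, an shRNA against METTL14 or a non-specific control shRNA (shCtrl), and was selected with puromycin. Cells received cycloheximide, which stalls elongating ribosomes, shortly before collection. Part of each lysate was kept as input, from which mRNA was isolated and fragmented by heat. The rest was digested with micrococcal nuclease and run on a sucrose gradient, and RNA from the 80S monosome fractions was depleted of rRNA and size-selected on a gel. Both kinds of RNA went through a small RNA library kit and were sequenced on a HiSeq4000. The design has 3 shRNAs, 2 fractions (input and footprints) and 2 replicates, which makes 12 libraries in 6 groups. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

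The deposited count table holds whole-number read counts per gene for 19854 gene identifiers with hg19 coordinates, and per the submitters' processing notes the counts came from FastQC 0.11.5, cutadapt 1.13, Bowtie 1.1.2 and featureCounts on hg19. A featureCounts version, the alignment settings and the use of strand are not given in the sources used here. Counting that ignores strand can mix a gene with an overlapping antisense gene, and near-identical copies can share or lose short reads, so members of such families are named as uncertain. Another 4 count columns match no sample of the series and were not used. The authors' deposited tables of translation efficiency, 1 per targeting shRNA, hold p-values and adjusted p-values, a linear ratio of footprints to input per group (the efficiency), and a log2 fold change of that ratio. Per the file headers and names these come from RiboDiff, a count model for ribosome profiling. The log2 fold change in the authors' deposited tables equalled the log2 ratio of the listed efficiencies for 19854 of 19854 genes, within 0.001.

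Gene symbols and biotypes came from GENCODE release 29, matched on the identifier without its version. They named 19311 identifiers, and 543 stayed without a symbol and took 0.52 to 0.639% of the counts of a library. Of all identifiers, 19236 were protein-coding, so long non-coding RNAs were not analysed here. All coordinates are those of the count table (hg19). Transcript length and GC content were taken from the longest coding transcript of 19239 genes in the same GENCODE release. Sequences compared between genes were those of all transcripts of a gene in that release.

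Total counts were 9405834 to 17393703 in the input libraries and 5135106 to 6790936 in the footprint libraries. A count of 3 corresponds to 0.173 to 0.319 CPM (counts scaled to the library total) in input and 0.442 to 0.584 CPM in footprints. For the shares of counts given per library, the 95% Wilson binomial intervals reach at most 0.0312 percentage points to either side. Reads carry no molecular identifiers, so these intervals and floors cover counting error only. The counts of the replicates of each group were compared by chi-square over genes with at least 20 counts, and every pair differed by more than sampling noise.

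Changes were tested with edgeR 4.0.16 (quasi-likelihood F test, 1 mean per group) under R 4.3.3. Input and footprint libraries were fitted separately with all 3 shRNAs, which then share an estimate of the spread on 3 residual degrees of freedom. Translation efficiency was tested as the interaction of fraction and shRNA in a fit of all 12 libraries with 6 residual degrees of freedom: the change in footprints minus the change in input. TMM factors were computed within each fraction, and genes were kept by filterByExpr with a minimum count of 10, for efficiency in both fractions. This left 18072 genes in input, 17464 in footprints and 17122 for efficiency. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 9 comparisons set each targeting shRNA against shCtrl and these against each other in input, footprints and efficiency. With 2 libraries per group, regrouping the samples cannot give a useful share, and no such count was made. CPM values are TMM-scaled and given as mean ± SD (n = 2 libraries). Changes are log2 fold changes with their standard error (SE).

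The groups, tests, gene lists, the rule for named genes and most alternatives were set before the data were examined. The rule names SETD2, METTL14 and MYC; for each comparison against shCtrl, up to 10 rises and 10 falls with the largest log2 change among called protein-coding genes with at least 5 CPM in a compared group (for efficiency, in both fractions) and the same direction in all pairs of libraries; up to 5 in each direction between shSETD2 and shMETTL14; and per list the 2 members on each side with the smallest p. Where the text gives only some of these, calls kept when any single library was left out were preferred, and some genes that the rule names are not reported here. Of 27 gene lists, 25 could be measured. They cover m6A writers, erasers and readers; H3K36 methylation enzymes and readers; mRNAs widely reported as m6A-modified; cytosolic ribosomal proteins; translation factors; mitochondrially encoded proteins; the nuclear-encoded respiratory chain; hepatocyte secreted proteins; liver transcription factors; cholesterol synthesis and uptake; fatty acid synthesis; ATF4 and the integrated stress response; endoplasmic reticulum (ER) chaperones and the unfolded protein response; p53 targets; interferon-stimulated genes; mitosis; DNA replication; MYC-driven nucleolar genes; replication-dependent histones; homologous recombination and mismatch repair; beta-catenin targets; glycolysis and hypoxia; and markers of HEK293T cells, of fibroblasts and stroma, and of leukocytes and endothelium. Lists of snoRNA host transcripts (15 names) and nuclear long non-coding RNAs (13 names) had 0 identifiers in the table. BOP1, PECAM1, HIST1H2BF, HIST1H2BG and HIST1H4B were not matched. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, which asks whether a list moved relative to all other genes, with Benjamini-Hochberg adjustment over lists within a comparison. The same test with the correlation estimated from the residuals is given beside each call; with it, 0 of the 105 camera calls were kept. fry was also run, whose directional p tests whether a list's genes move on balance 1 way without comparing them with other genes.

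Alternatives were DESeq2 1.42.0, RLE factors, scaling by library size alone, no filter on low counts, a stricter filter (a mean of at least 50 counts in every group), only the 2 shRNAs compared, genes above 1% of a library left out, the replicate number as a block, each library left out in turn and, for efficiency, the lysate as a block, TMM factors over all libraries and limma voom with the lysate as a random block. The stricter filter thus also drops genes that are low in 1 group only. Removal of smooth trends with transcript length and GC content was added after seeing the data. Where leaving a library out leaves a single sample in a group, that sample is assumed to vary like the other groups. The efficiency fit shares 1 spread per gene between input and footprints. Fitted apart, their common dispersion, a measure of the spread between replicates, was 0.0073 in input and 0.035 in footprints. Leaving out a library changes the mix of both fractions in the shared spread. Efficiency counts with 1 library left out therefore do not measure dependence on that library alone. Per the labels' protocol input is part of a lysate whose rest gave footprints. That libraries with the same shRNA and replicate number share a lysate is read from the numbers and not shown by the values. Their deviations from the group means correlated at -0.03, 0.04 and 0.04 over 13171 genes for shCtrl, shMETTL14 and shSETD2.

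The similarity of the changes with the labels shSETD2 and shMETTL14 was set beside 50 simulated draws of unchanged groups against the same shCtrl libraries. The edgeR fits and camera were tested on simulated data for shSETD2 against shCtrl only: in input (17884 genes), 75% of the genes changed 2-fold and 94.9% of those changed 4-fold were recovered, among those kept by the filter of 100 each. For footprints of that comparison (17172 genes) the shares were 51% and 83.8%, and for efficiency (16831 genes) 35.7% and 81.4%. Genes simulated as unchanged made up 1.17, 4.29 and 1.72% of the calls. The simulated counts gave genes of equal abundance the same spread. Single genes whose replicates differ more are therefore not covered, and the real shares may be worse. The removal of trends was tested on simulated input of shMETTL14 against shCtrl. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.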

Results

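Active ribosome profiling counts short mRNA fragments protected by 80S ribosomes (footprints) beside fragmented mRNA from the same lysate (input). It was applied to HepG2 liver cancer cells with stable expression of an shRNA against SETD2, the main H3K36 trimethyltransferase, an shRNA against METTL14, a subunit of the nuclear m6A methyltransferase complex, or a control shRNA (shCtrl). The design asks how a stable shRNA against either gene changes mRNA levels, ribosome occupancy and their ratio, the translation efficiency. Each shRNA had 2 input and 2 footprint libraries. Input totals were 9405834 and 10409023 counts for shCtrl, 17393703 and 12945849 for shMETTL14 and 14327505 and 16946500 for shSETD2. Footprint totals were 5999477 and 6790936 counts for shCtrl, 5135106 and 5178763 for shMETTL14 and 5185035 and 5830937 for shSETD2. Replicates correlated at a Pearson r of 0.962 to 0.994 on log2 CPM across genes, which are not independent replicates.

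Ribosomal protein genes took 16.2 and 16.9% of the counts of the shCtrl input libraries, 15.5 and 16.6% of those labelled shSETD2, and 8.67 and 7.99% of those labelled shMETTL14. In footprints the shares were 5.35 and 5.44% for shCtrl, 4.32 and 4.53% for the label shSETD2 and 2.69 and 2.64% for the label shMETTL14. The 13 mitochondrially encoded mRNAs held 3.50 and 6.43% of the footprint counts of shCtrl, 6.38 and 5.98% with the label shSETD2 and 1.39 and 1.46% with the label shMETTL14. MTRNR2L genes, nuclear copies of the mitochondrial large ribosomal RNA, held 18.7% of shCtrl footprint replicate 1 against 9.28% of replicate 2 and 6.59 to 13.2% of the other footprint libraries. The shCtrl footprint replicates had a chi-square per degree of freedom of 29.6 over 16312 genes, against 6.59 to 9.06 in the other groups, a measure that weights abundant genes. By Pearson r on log2 CPM they stood at 0.971, against 0.963 for footprints labelled shMETTL14 and 0.962 for those labelled shSETD2. Mitochondrially encoded mRNAs are translated by mitochondrial ribosomes, so their counts in the 80S fraction, and ratios formed from them, are not shown to be ribosome occupancy.

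**Figure D1:**
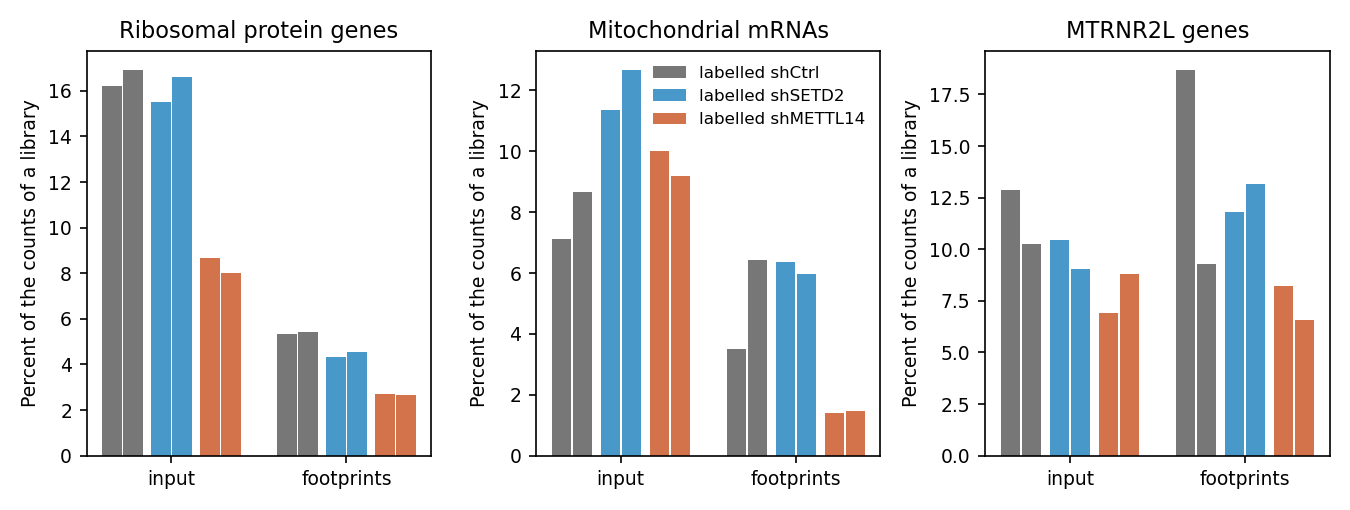
Percent of the counts of each library (y axis, from 0) taken by ribosomal protein genes, mitochondrial mRNAs and MTRNR2L genes, with 1 bar per library and colours for the shRNA label. Input libraries labelled shMETTL14 gave 8.67 and 7.99% to ribosomal protein genes, and shCtrl footprint replicate 1 gave 18.7% to MTRNR2L genes.

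Neither targeted gene was lower in the libraries labelled with its shRNA. METTL14 (ENSG00000145388.14, hg19 chromosome 4, 119606523 to 119636588) stood at 79.1 ± 0.933 CPM in input labelled shMETTL14 against 29 ± 2.32 CPM in shCtrl input and 30.5 ± 0.388 CPM in input labelled shSETD2 (mean ± SD, n = 2). Its log2 change with the label shMETTL14 was 1.45 (SE 0.12, edgeR adjusted p = 1.8e-11) in input and 2.09 (SE 0.21, adjusted p = 2.4e-04) in footprints, where it stood at 357 ± 35.3 against 83.6 ± 18.3 CPM. SETD2 (ENSG00000181555.19, hg19 chromosome 3, 47058179 to 47205457) stood at 27.2 ± 1.81 CPM in input labelled shSETD2 against 24.3 ± 1.15 CPM in shCtrl input, a change of 0.16 (SE 0.13, adjusted p = 0.49). SETD2 footprints were 91.9 and 252 CPM in the replicates labelled shSETD2 against 57.9 ± 4.85 CPM in shCtrl, a change of 1.57 (SE 0.36, adjusted p = 0.018). That call ended with DESeq2 (adjusted p = 0.084), without shCtrl footprint replicate 1 (adjusted p = 0.10), without replicate 2 of shCtrl (0.077) and without replicate 2 labelled shSETD2 (change 0.66, adjusted p = 0.10). With the label shMETTL14, SETD2 input changed by 0.37 (SE 0.13, adjusted p = 0.018). The latter call ended without shCtrl input replicate 1 (adjusted p = 0.104), without input replicate 2 labelled shMETTL14 (0.113) and with length and GC trends removed (0.253). METTL14 changed by 0.07 (SE 0.12, adjusted p = 0.78) in input labelled shSETD2. Since METTL14 goes against its label and SETD2 was not shown to be lower with its own, every direction below refers to the libraries as labelled. None is a statement on loss of SETD2 or METTL14.

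**Figure D2:**
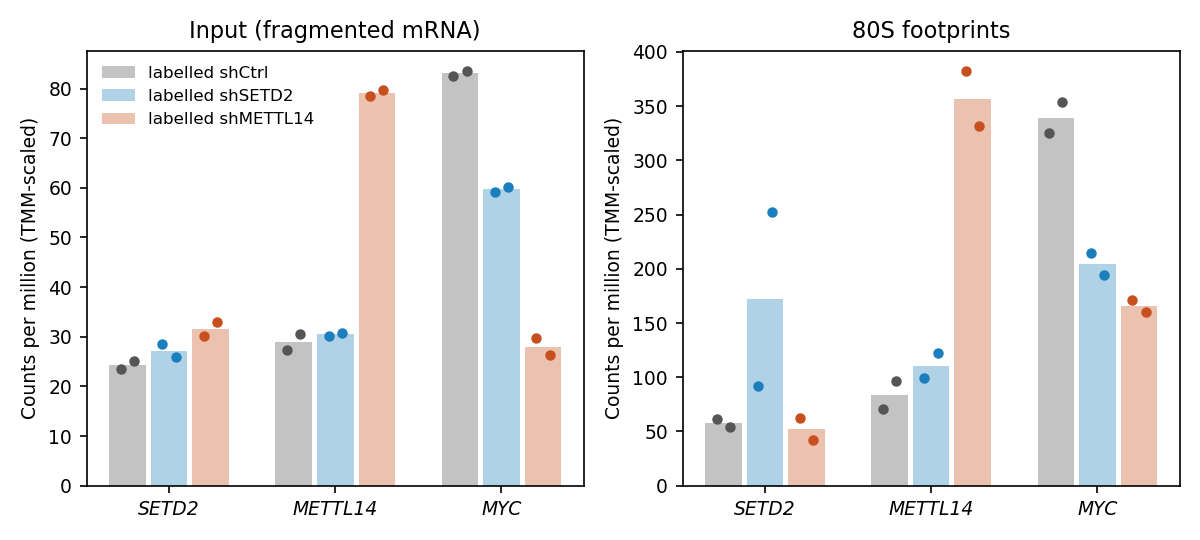
TMM-scaled CPM (y axis, from 0) of SETD2, METTL14 and MYC in input and footprints, with bars for group means, points for the 2 libraries of a group and colours for the shRNA label. METTL14 reached 79.1 CPM in input labelled shMETTL14 against 29 CPM in shCtrl, and SETD2 did not fall with the label shSETD2 (27.2 against 24.3 CPM in input).

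MYC (ENSG00000136997.15, hg19 chromosome 8, 128747680 to 128753680), a proto-oncogene and transcription factor whose mRNA is widely reported to carry m6A, fell in input to 28 ± 2.46 CPM with the label shMETTL14 and 59.7 ± 0.744 CPM with the label shSETD2, against 83 ± 0.58 CPM in shCtrl (n = 2). The log2 changes were -1.56 (SE 0.11, adjusted p = 2.7e-12) and -0.48 (SE 0.11, adjusted p = 0.0022), the latter at adjusted p = 0.052 without input replicate 1 labelled shSETD2. MYC footprints changed by -1.03 (SE 0.17, adjusted p = 0.0030) and -0.73 (SE 0.17, adjusted p = 0.019). The footprint call for shSETD2 ended without any 1 of its 4 libraries, at adjusted p = 0.076 and 0.063 without shCtrl replicates 1 and 2 and 0.118 and 0.099 without replicates 1 and 2 labelled shSETD2. Efficiency of MYC changed by 0.48 (SE 0.18, adjusted p = 0.11) and -0.25 (SE 0.18, adjusted p = 0.40), both short of the threshold; with the stricter filter the first was 0.64 (adjusted p = 0.018).

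DIO1, the type 1 iodothyronine deiodinase, rose in input labelled shSETD2 to 26.4 ± 2 from 2.31 ± 0.728 CPM in shCtrl, a log2 change of 3.52 (SE 0.21, adjusted p = 1.1e-13). ANGPTL8, a secreted regulator of lipoprotein lipase, rose to 68.2 ± 2.3 from 10 ± 1.17 CPM (2.77, SE 0.14), and TXNIP, an inhibitor of glucose uptake, by 2.64 (SE 0.18). Among the largest rises were also the gastrin gene GAST (3.09, SE 0.39), the organic anion transporter SLC22A7 (2.90, SE 0.25), the coagulation factor subunit F13B (2.84, SE 0.28) and the serum amyloid SAA4 (2.60, SE 0.29). The largest falls included INSL6, an insulin-like peptide (-3.29, SE 0.44), PRR32 (-2.36, SE 0.29), SH3GL2, an endophilin of synaptic vesicle endocytosis (-2.21, SE 0.24), and LCN15, a lipocalin (-2.15, SE 0.18). Footprints fell for LCN15, but stood at 4.05 against 0.598 CPM for PRR32 and 6.15 against 4.53 CPM for SH3GL2. The 0.598 CPM of PRR32 in shCtrl lies near the floor of 3 counts. The shCtrl inputs scattered, with 8.05 ± 5.71 CPM for INSL6, 15.3 ± 6.99 CPM for PRR32 and 24.4 ± 9.74 CPM for SH3GL2. Of 18072 genes, 1315 rose and 1391 fell. With scaling by library size alone the split was 1075 higher and 2193 lower. DESeq2 called 1738, and 1663 and 1281 were called without input replicate 1 or 2 labelled shSETD2.

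Of 41 hepatocyte secreted proteins, 26 rose and 0 fell in input labelled shSETD2 (29 and 0 adjusted over the list alone), with a median change of 0.81. ITIH3, an inter-alpha-trypsin inhibitor chain that binds hyaluronan, rose by 2.13 (SE 0.12) and APOM, an apolipoprotein of HDL, by 1.78 (SE 0.12). The list was called by camera at adjusted p = 7.6e-43, and adjusted p = 0.21 with an estimated correlation. In cholesterol synthesis and uptake, 19 of 24 genes rose and 1 fell (20 and 1 adjusted over the list alone; median 0.74, camera adjusted p = 2.4e-32, adjusted p = 0.20 with an estimated correlation). MSMO1, a sterol oxidase, rose by 1.59 (SE 0.11). Fatty acid synthesis had 10 rises among 16 genes (11 adjusted over the list alone; median 0.46, adjusted p = 5.4e-09, adjusted p = 0.21 with an estimated correlation), with ACSS2, which makes acetyl-CoA from acetate, at 1.36 (SE 0.13) and the desaturase SCD at 1.23 (SE 0.12). All 12 called members of the 13 mitochondrially encoded mRNAs rose (13 adjusted over the list alone; median 0.75, adjusted p = 3.9e-15, adjusted p = 0.32 with an estimated correlation), but 7 without shCtrl input replicate 1 and 7 without input replicate 2 labelled shSETD2.

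In the ATF4 and integrated stress response list, 15 of 28 genes fell and 0 rose in input labelled shSETD2 (18 and 1 adjusted over the list alone; median -0.42, camera adjusted p = 2.7e-07, adjusted p = 0.32 with an estimated correlation), among them ASNS, asparagine synthetase (-1.10, SE 0.11), and DDIT3, the CHOP transcription factor (-0.86, SE 0.13). Without input replicate 2 labelled shSETD2, 8 were called. ER chaperones and unfolded protein response genes had 9 falls among 19 (9 adjusted over the list alone; median -0.25, adjusted p = 2.9e-07, adjusted p = 0.46 with an estimated correlation), led by HSP90B1 (-1.03, SE 0.13), and 5 without input replicate 1 labelled shSETD2. Glycolysis and hypoxia gave 5 falls and 2 rises among 26 (8 and 3 adjusted over the list alone; median -0.15, adjusted p = 0.0079, adjusted p = 0.46 with an estimated correlation), with the glucose transporters SLC2A3 at -1.06 (SE 0.11) and SLC2A1 at -1.05 (SE 0.12). Camera also called DNA replication (median 0.24, adjusted p = 7.9e-05, adjusted p = 0.21 with an estimated correlation) and mitosis (median 0.15, adjusted p = 0.014, adjusted p = 0.42 with an estimated correlation). Medians were negative for MYC-driven nucleolar genes (median -0.15, adjusted p = 0.0053, adjusted p = 0.46 with an estimated correlation), beta-catenin targets (median -0.18, adjusted p = 0.020, adjusted p = 0.42 with an estimated correlation) and translation factors (median -0.15, adjusted p = 0.027, adjusted p = 0.75 with an estimated correlation). Members called in either direction numbered 9 for DNA replication, 8 for mitosis, 10 for nucleolar genes, 6 for beta-catenin targets and 11 for translation factors. Each of these 5 lists had fewer without 1 of the compared input libraries. The nucleolar helicase DDX21 fell by 0.72 (SE 0.11) and thymidine kinase TK1 rose by 1.06 (SE 0.14).

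No call was made for liver transcription factors (camera adjusted p = 0.14), although HNF4A (0.91, SE 0.11) and CEBPA (0.89, SE 0.12) rose and CEBPB fell by 0.87 (SE 0.11). Ribosomal protein genes had a median of 0.04 (-0.05 with scaling by library size alone) at adjusted p = 0.59, and RPLP0, of the ribosomal stalk, rose by 0.76 (SE 0.14). Lists without a call were also m6A-modified mRNAs (0.14), H3K36 enzymes and readers (0.26), recombination and mismatch repair (0.26), m6A writers, erasers and readers (0.44), histones (0.51), p53 targets (0.51), the nuclear-encoded respiratory chain (0.57) and interferon-stimulated genes (0.94). Markers of HEK293T cells (0.19), leukocytes and endothelium (0.79) and fibroblasts and stroma (0.84) were not called either. Median, mean and test did not share a sign for p53 targets, the respiratory chain and the markers of leukocytes and of fibroblasts.

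In input labelled shMETTL14, TXNIP rose to 61.6 ± 0.891 from 4.07 ± 1.28 CPM in shCtrl, a log2 change of 3.93 (SE 0.16, adjusted p = 2.9e-17), and ITIH3 to 164 ± 13.5 from 24.9 ± 1.04 CPM (2.72, SE 0.12). Also rising were RAMP1, a receptor-modifying protein of calcitonin-type receptors (3.74, SE 0.31), LGALS2, a galectin (2.56, SE 0.15), and CREB3L3, a liver transcription factor of fasting metabolism (2.38, SE 0.17). PRR32 (-4.33, SE 0.34), MS4A15 (-4.17, SE 0.23), SH3GL2 (-4.15, SE 0.28), the transcription factor DMRT2 (-3.29, SE 0.33) and the kallikrein KLK6 (-3.27, SE 0.32) were among the genes that fell. None of these 5 was lower in footprints than in shCtrl: PRR32 stood at 1.92 against 0.598 CPM, MS4A15 at 13.8 against 8.06, SH3GL2 at 5.16 against 4.53, DMRT2 at 3.32 against 2.75 and KLK6 at 6.92 against 6.15. Their falls were therefore seen in input only, where shCtrl gave 15.3 ± 6.99 CPM for PRR32, 24.4 ± 9.74 CPM for SH3GL2 and 16.5 ± 6.89 CPM for KLK6. In shCtrl footprints PRR32 lay near the floor of 3 counts (0.442 to 0.584 CPM), so a fall there could not be seen. Of 18072 genes, 3549 rose and 3854 fell. With scaling by library size alone the split was 7746 higher and 1593 lower.

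Each of the 79 cytosolic ribosomal protein genes fell in input labelled shMETTL14 (79 adjusted over the list alone), with a median change of -1.37. RPL30 fell by 2.24 (SE 0.13, adjusted p = 4.5e-14) and RPL26 by 2.03 (SE 0.13). Camera gave the list adjusted p = 3.0e-89, and adjusted p = 0.43 with an estimated correlation, while fry gave adjusted p = 0.0049. Of 36 translation factors, 23 fell and 3 rose (23 and 3 adjusted over the list alone; median -0.50, adjusted p = 2.4e-07, adjusted p = 0.51 with an estimated correlation). EIF1, which guards start codon choice, fell by 1.87 (SE 0.12), and EIF5B, which joins the ribosomal subunits, rose by 1.81 (SE 0.12). The nuclear-encoded respiratory chain had 33 falls and 3 rises among 46 genes (34 and 3 adjusted over the list alone; median -0.55, adjusted p = 6.1e-09, adjusted p = 0.51 with an estimated correlation), with NDUFS7 at -1.40 and SDHA at 0.71 (SE 0.11).

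ATF4 and integrated stress response genes also fell with the label shMETTL14, 24 of 28 with 1 rise (25 and 1 adjusted over the list alone; median -0.93, camera adjusted p = 5.5e-24, adjusted p = 0.25 with an estimated correlation). DDIT4, an inhibitor of mTORC1, fell by 2.37 (SE 0.12), and ASNS by 2.17 (SE 0.12). ER chaperones and unfolded protein response genes had 17 falls among 19 (18 adjusted over the list alone; median -0.75, adjusted p = 1.1e-10, adjusted p = 0.51 with an estimated correlation), among them HERPUD1, of ER-associated degradation (-1.75, SE 0.12), and HSPA5, the BiP chaperone (-1.55, SE 0.13). Replication-dependent histones had 23 falls among 28 (24 adjusted over the list alone; median -0.90, adjusted p = 2.4e-05, adjusted p = 0.51 with an estimated correlation), although these genes share near-identical sequence and are uncertain. Glycolysis and hypoxia had 15 falls and 2 rises among 26 (16 and 2 adjusted over the list alone), with GAPDH at -1.18 (SE 0.14). Its median was -0.41, or 0.01 with scaling by library size alone, where the median of all genes was 0.35 (camera adjusted p = 0.0060, adjusted p = 0.51 with an estimated correlation).

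Several chromatin and RNA modification genes rose with the label shMETTL14. Of 21 m6A writers, erasers and readers, 10 rose and 4 fell (11 and 5 adjusted over the list alone; median 0.34, camera adjusted p = 0.012, adjusted p = 0.51 with an estimated correlation). ZC3H13, which anchors the writer complex in the nucleus, rose by 1.55 (SE 0.12), and RBM15B, which recruits it to RNA, fell by 0.75 (SE 0.12). H3K36 methylation enzymes and readers had 9 rises and 2 falls among 17 (9 and 2 adjusted over the list alone; median 0.37, adjusted p = 0.038, adjusted p = 0.50 with an estimated correlation), including the methyltransferase ASH1L (0.77, SE 0.12). Recombination and mismatch repair had 12 rises and 1 fall among 26 (12 and 1 adjusted over the list alone; median 0.34, adjusted p = 0.0043, adjusted p = 0.43 with an estimated correlation). There RAD50, of the MRN complex, rose by 1.12 (SE 0.12).

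Hepatocyte secreted proteins counted 15 rises and 11 falls in input labelled shMETTL14 and were not called (camera adjusted p = 0.063), with FGB, the fibrinogen beta chain, at 1.35 (SE 0.12) and antithrombin, SERPINC1, at -1.33 (SE 0.15). DNA replication had 9 rises and 3 falls (0.069) and mitosis 13 and 8 (0.094), with MKI67 at 1.53 (SE 0.13) and PLK1 at -1.12 (SE 0.12). Nucleolar genes had 6 and 10 (0.20), beta-catenin targets 2 and 4 (0.24; DKK1 -1.72, SE 0.11) and cholesterol synthesis 4 and 11 (0.25). Fatty acid synthesis counted 4 and 2 (0.55), p53 targets 6 and 6 (0.55), interferon-stimulated genes 7 and 9 (0.82; USP18 1.18, SE 0.17) and m6A-modified mRNAs 4 and 4 (0.93). Liver transcription factors counted 7 rises and 4 falls (0.34), with 7 calls without input replicate 1 labelled shMETTL14. Mitochondrially encoded mRNAs counted 2 and 3 (0.55), with 3 calls without shCtrl input replicate 2 and 1 without input replicate 2 labelled shMETTL14. Among markers of other cells, 1 fibroblast gene rose and 2 fell (0.34), with TAGLN, of smooth muscle, at -2.18 (SE 0.14). Further, 2 HEK293T genes fell (0.25; 1 without shCtrl input replicate 1 or input replicate 2 labelled shMETTL14), and leukocyte markers were not called (0.93). Median, mean and test did not share a sign for liver transcription factors, fatty acid synthesis and interferon-stimulated genes.

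Set directly against each other in input, libraries labelled shSETD2 lay above those labelled shMETTL14 for 3545 genes and below for 3292, of 18072. With scaling by library size alone the split was 1300 and 8738. The iron storage gene FTL stood at 13830 ± 1282 against 1573 ± 105 CPM (3.14, SE 0.18), and GAST (3.93, SE 0.38), the metalloprotease MEP1A (3.54, SE 0.17) and AGR2, an ER disulfide isomerase (3.49, SE 0.14), were also higher. EIF5B (-2.20, SE 0.12), NKTR, a cyclophilin with an SR domain (-2.29, SE 0.14), and tropomyosin TPM2 (-2.35, SE 0.19) were lower. All 79 ribosomal protein genes were higher (79 adjusted over the list alone; median 1.44, camera adjusted p = 2.4e-85, adjusted p = 0.25 with an estimated correlation), with RPLP0 at 2.38 (SE 0.14). Cholesterol synthesis and uptake had 22 of 24 higher (22 adjusted over the list alone; median 0.92, adjusted p = 5.2e-18, adjusted p = 0.25 with an estimated correlation; EBP, a sterol isomerase, 1.57, SE 0.11). ATF4 and integrated stress response had 20 of 28 higher (21 adjusted over the list alone; median 0.57, adjusted p = 1.4e-10, adjusted p = 0.25 with an estimated correlation; DDIT4 2.11, SE 0.12), and mitochondrially encoded mRNAs 12 of 13 (13 adjusted over the list alone; median 0.95, adjusted p = 7.6e-08, adjusted p = 0.46 with an estimated correlation).

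**Figure D3:**
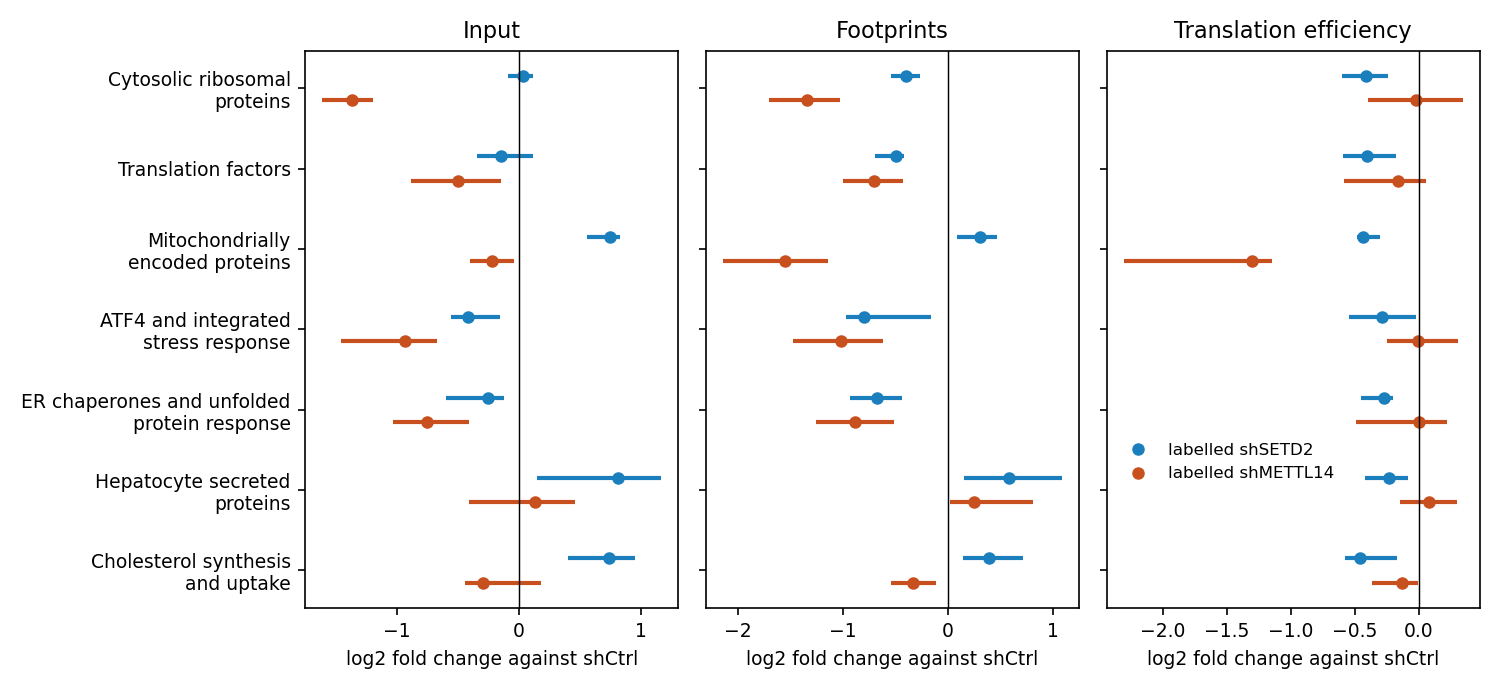
Median log2 fold change against shCtrl (x axis, separate scale per panel; points) with the quartiles over members (bars) for 7 gene lists in input, footprints and translation efficiency, with colours for the shRNA label. Ribosomal protein genes lay at -1.37 in input and -1.34 in footprints with the label shMETTL14; with scaling by library size alone the input medians of ribosomal proteins for shSETD2 (-0.05) and of mitochondrial (0.20) and cholesterol genes (0.12) for shMETTL14, the footprint median of cholesterol genes for shMETTL14 (0.03) and the efficiency median of hepatocyte proteins for shSETD2 (0.01) change sign, and the efficiency medians of ER, ATF4, ribosomal protein and hepatocyte genes for shMETTL14, between -0.02 and 0.08, change sign under at least 1 scaling.

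In 80S footprints labelled shSETD2, DKK4, a secreted Wnt inhibitor, rose by 3.54 (SE 0.55, adjusted p = 0.0046) against shCtrl. VCAN, the matrix proteoglycan versican, fell to 77.7 ± 2 from 404 ± 27.3 CPM, a change of -2.38 (SE 0.18, adjusted p = 1.4e-04). The secreted phospholipase PLA2G2A (-2.87, SE 0.47), LCN15 (-2.40, SE 0.36), the RhoA exchange factor ARHGEF2 (-2.17, SE 0.24), the sulfatase ARSI (-2.16, SE 0.18) and the immune receptor OSCAR (-2.03, SE 0.30) also fell. The stress gene TRIB3, a pseudokinase induced by ATF4, fell by 1.49 (SE 0.17), GDF15, a secreted stress cytokine, by 1.40 (SE 0.19), SLC2A1 by 1.71 (SE 0.21) and VEGFA by 1.29 (SE 0.18). AXIN2 and CCND1, targets of beta-catenin, each fell by 1.25 (SE 0.17 and 0.18). APOM rose by 1.46 (SE 0.20). Of 17464 genes, 1013 rose and 1349 fell. The split was 1175 and 660 with scaling by library size alone, 902 and 773 with the stricter filter and 844 and 2289 with length and GC trends removed. Calls numbered 220 without shCtrl footprint replicate 1, the library with the highest MTRNR2L share (18.7%), 1367 without shCtrl replicate 2 and 242 without replicate 1 labelled shSETD2.

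Hepatocyte secreted proteins had 13 rises and 1 fall among 41 in footprints labelled shSETD2 (20 and 1 adjusted over the list alone; median 0.58, camera adjusted p = 1.0e-08, adjusted p = 0.34 with an estimated correlation). ATF4 and integrated stress response genes had 15 falls among 28 (18 adjusted over the list alone; median -0.80, adjusted p = 2.9e-09, adjusted p = 0.28 with an estimated correlation). ER chaperones had 11 among 19 (12 adjusted over the list alone; median -0.68, adjusted p = 6.5e-10, adjusted p = 0.28 with an estimated correlation), and translation factors 12 among 36 (21 adjusted over the list alone; median -0.50, adjusted p = 2.9e-09, adjusted p = 0.28 with an estimated correlation). Ribosomal protein genes had 9 falls among 78 (9 adjusted over the list alone; median -0.40, adjusted p = 8.0e-09, adjusted p = 0.28 with an estimated correlation). Glycolysis and hypoxia had 9 falls among 26 (13 adjusted over the list alone; median -0.45, adjusted p = 5.6e-06, adjusted p = 0.34 with an estimated correlation). Without shCtrl replicate 1, these 6 lists in turn had 5, 3, 6, 1, 0 and 4 members called. Without replicate 1 labelled shSETD2 they had 6, 4, 0, 0, 0 and 3. Omitting shCtrl replicate 2 left 9 ATF4, 5 ER and 7 translation factor genes, and omitting replicate 2 labelled shSETD2 left 9 hepatocyte, 4 translation factor and 0 ribosomal protein genes.

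Camera also called cholesterol synthesis (median 0.39, adjusted p = 4.9e-04, adjusted p = 0.42 with an estimated correlation) and nucleolar genes (-0.52, adjusted p = 2.0e-07, adjusted p = 0.28 with an estimated correlation) in footprints labelled shSETD2. The same held for p53 targets (-0.42, adjusted p = 2.3e-06, adjusted p = 0.28 with an estimated correlation) and beta-catenin targets (-0.66, adjusted p = 7.8e-06, adjusted p = 0.28 with an estimated correlation). Weaker calls went to histones (0.31, adjusted p = 0.0066, adjusted p = 0.47 with an estimated correlation) and the nuclear-encoded respiratory chain (-0.16, or 0.01 with scaling by library size alone; adjusted p = 0.029, adjusted p = 0.63 with an estimated correlation). Methylation lists called were m6A-modified mRNAs (-0.30, adjusted p = 0.040, adjusted p = 0.28 with an estimated correlation) and m6A writers, erasers and readers (-0.31, adjusted p = 0.043, adjusted p = 0.28 with an estimated correlation). H3K36 enzymes and readers had a median of -0.47 (adjusted p = 0.047, adjusted p = 0.28 with an estimated correlation), mitochondrially encoded mRNAs 0.30 (adjusted p = 0.047, adjusted p = 0.66 with an estimated correlation) and fatty acid synthesis 0.33 (adjusted p = 0.043, adjusted p = 0.45 with an estimated correlation). The last 2 calls ended without a filter (adjusted p = 0.055 and 0.072). Leukocyte and endothelial markers had a median of 0.93 (adjusted p = 0.017, adjusted p = 0.28 with an estimated correlation), with only 2 members called. Members called in either direction numbered 9 for beta-catenin targets, 8 each for cholesterol synthesis and nucleolar genes, and 6 each for p53 targets and m6A-modified mRNAs. The 2 other methylation lists had 4 each, the respiratory chain and fatty acid synthesis 3 each, histones 1 and mitochondrially encoded mRNAs 0. Each of these lists with a called member had fewer without 1 of the compared libraries, for most of them shCtrl footprint replicate 1. These counts therefore depend on single libraries.

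In footprints labelled shMETTL14, TXNIP rose by 3.73 (SE 0.22, adjusted p = 1.5e-05) to 98.6 ± 18 CPM and the kinase-like STYK1 by 3.18 (SE 0.48). FTL fell to 715 ± 79.2 from 4064 ± 240 CPM (-2.51, SE 0.22), and C12orf57 (-2.92, SE 0.23), DDIT3 (-2.74, SE 0.27), ATF3, a stress transcription factor (-2.68, SE 0.35), the ribosome assembly factor WDR74 (-2.58, SE 0.38) and FOSL1, of the AP-1 complex (-2.40, SE 0.35), were among the largest falls. Of 17464 genes, 805 rose and 1397 fell. The split was 3210 and 590 with scaling by library size alone and 490 and 1703 with length and GC trends removed. Without shCtrl footprint replicate 1 or 2, 1117 and 982 genes were called, and without replicate 1 or 2 labelled shMETTL14, 1361 and 907.

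Of 78 ribosomal protein genes, 74 fell and 0 rose in footprints labelled shMETTL14 (76 and 0 adjusted over the list alone), with a median of -1.34 (camera adjusted p = 1.3e-91, adjusted p = 0.059 with an estimated correlation). RPL19 fell by 2.37 (SE 0.20) and RPS27 by 2.17 (SE 0.19). Mitochondrially encoded mRNAs had 12 falls among 13 (13 adjusted over the list alone; median -1.55, adjusted p = 3.8e-21, adjusted p = 0.36 with an estimated correlation), with MT-ATP8 at -2.74 and MT-CO1 at -2.69 (SE 0.32 each). ATF4 and integrated stress response genes had 19 falls among 28 (21 adjusted over the list alone; median -1.02, adjusted p = 4.2e-23, adjusted p = 0.059 with an estimated correlation), among them the cystine transporter SLC7A11 (-1.94, SE 0.17) and TRIB3 (-1.93, SE 0.17). ER chaperones had 13 falls among 19 (15 adjusted over the list alone; median -0.88, adjusted p = 2.4e-15, adjusted p = 0.36 with an estimated correlation), with 8 calls without replicate 2 labelled shMETTL14. Translation factors had 22 falls and 1 rise among 36 (27 and 2 adjusted over the list alone; median -0.70, adjusted p = 2.4e-15, adjusted p = 0.36 with an estimated correlation; EIF1 -1.85, SE 0.18). Nucleolar genes had 12 falls and 1 rise among 27 (13 and 1 adjusted over the list alone; median -0.62, adjusted p = 3.8e-08, adjusted p = 0.44 with an estimated correlation), with NOP56, of box C/D snoRNPs, at -2.02 (SE 0.20). Calls in these last lists numbered 14 and 8 without shCtrl replicate 1, 14 and 8 without shCtrl replicate 2, and 10 and 5 without replicate 2 labelled shMETTL14; nucleolar calls were also 8 without replicate 1 of that label.

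Hepatocyte secreted proteins had 12 rises and 5 falls among 41 in these footprints (17 and 6 adjusted over the list alone; median 0.25, camera adjusted p = 0.0030, adjusted p = 0.56 with an estimated correlation), and 11 calls without shCtrl replicate 2. ITIH3 rose by 2.63 (SE 0.18) and ORM1, an acute-phase glycoprotein, fell by 1.38 (SE 0.20). The cholesterol list had a median of -0.33, or 0.03 with scaling by library size alone (adjusted p = 0.0067, adjusted p = 0.56 with an estimated correlation). Further calls at adjusted p = 0.56 with an estimated correlation went to the nuclear-encoded respiratory chain (median -0.36, adjusted p = 4.9e-04), histones (-0.37, adjusted p = 9.3e-04), beta-catenin targets (-0.23, or 0.14 with scaling by library size alone, adjusted p = 0.0074), DNA replication (0.24, adjusted p = 0.046) and glycolysis (-0.09, or 0.27 with scaling by library size alone, adjusted p = 0.046). The other 12 lists had camera adjusted p-values above the threshold, the lowest for p53 targets (0.068). Without a filter the call of DNA replication ended (adjusted p = 0.050) and p53 targets were called (0.044).

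Between the labels shSETD2 and shMETTL14, footprints labelled shSETD2 lay above those labelled shMETTL14 for 819 genes and below for 1043. The split was 461 and 2200 with scaling by library size alone, 1001 and 846 with genes above 1% of a library left out and 1101 and 838 with the stricter filter. DKK4 (3.76, SE 0.56) was higher, while ITGA3, an integrin chain (-2.60, SE 0.25), the tetraspanin TSPAN15 (-2.63, SE 0.39) and GZMK, a granzyme (-3.08, SE 0.37), were lower. All 13 mitochondrially encoded mRNAs were higher (13 adjusted over the list alone; median 1.72, camera adjusted p = 1.8e-33, adjusted p = 0.32 with an estimated correlation; MT-ATP8 2.78, SE 0.32). Ribosomal protein genes had 61 of 78 higher (68 higher and 1 lower adjusted over the list alone; median 0.91, adjusted p = 8.8e-53, adjusted p = 0.32 with an estimated correlation), but 38 without replicate 2 labelled shMETTL14 and 37 without replicate 1 or 2 labelled shSETD2. Calls over all genes numbered 586 and 1102 without replicates 1 and 2 labelled shMETTL14 and 561 without replicate 1 labelled shSETD2.

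Translation efficiency with the label shSETD2 fell for IFRD2, a ribosome-binding protein, by 1.74 (SE 0.25, adjusted p = 0.014). Its input was 41.2 against 23.5 CPM in shCtrl and its footprints 30.9 against 59.3 CPM. TSPAN7, a tetraspanin (-1.51, SE 0.24), TRIM8, an E3 ubiquitin ligase (-1.34, SE 0.20), and TRIB3 (-1.12, SE 0.19) also fell, and the ceramide synthase CERS3 (4.05, SE 0.70), TRIM50 (3.50, SE 0.64) and PCDHAC1, a protocadherin (3.06, SE 0.54), rose. Of 17122 genes, 389 rose and 546 fell. The split was 338 and 84 with scaling by library size alone, 232 and 211 with the stricter filter and 429 and 1389 with length and GC trends removed and the lysate as a block. Counts with a library left out also follow the spread that input and footprints share in this fit, and do not measure dependence on that library alone. No edgeR call remained without shCtrl input replicate 1 (0 genes, with 2848 at an unadjusted p under 0.05) or input replicate 2 labelled shSETD2 (0, with 3041), against 1248 calls by DESeq2 over all libraries; the genes just named are lost there. Calls also numbered 604 without shCtrl input replicate 2, 370 without input replicate 1 or 2 labelled shMETTL14, 145 without input replicate 1 labelled shSETD2, 244 without shCtrl footprint replicate 1, and 79 and 1892 without footprint replicates 1 and 2 labelled shSETD2.

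Of the lists called for efficiency with the label shSETD2, only histones had a positive median (0.23, camera adjusted p = 0.0498, adjusted p = 0.57 with an estimated correlation), and that call ended without a filter (adjusted p = 0.074). Negative medians were called for ribosomal proteins (-0.41, camera adjusted p = 3.5e-09, adjusted p = 0.48 with an estimated correlation), translation factors (-0.40, adjusted p = 1.1e-05, adjusted p = 0.48 with an estimated correlation) and p53 targets (-0.58, adjusted p = 6.8e-05, adjusted p = 0.48 with an estimated correlation). Next were cholesterol synthesis (-0.46, adjusted p = 3.0e-04, adjusted p = 0.48 with an estimated correlation) and beta-catenin targets (-0.45, adjusted p = 0.0024, adjusted p = 0.48 with an estimated correlation). Nucleolar genes (-0.26, adjusted p = 0.0024, adjusted p = 0.48 with an estimated correlation), ER chaperones (-0.27, adjusted p = 0.0051, adjusted p = 0.50 with an estimated correlation) and ATF4 targets (-0.29, adjusted p = 0.0051, adjusted p = 0.48 with an estimated correlation) followed. So did glycolysis (-0.28, adjusted p = 0.024, adjusted p = 0.50 with an estimated correlation) and mitochondrial mRNAs (-0.44, adjusted p = 0.044, adjusted p = 0.57 with an estimated correlation). For hepatocyte proteins (-0.23, adjusted p = 0.023, adjusted p = 0.57 with an estimated correlation) and DNA replication (-0.24, adjusted p = 0.023, adjusted p = 0.48 with an estimated correlation) the median was 0.01 and 0.00 with scaling by library size alone. Few members of these lists were called in either direction. The numbers were 4 for translation factors, 3 each for ribosomal proteins, p53 targets and beta-catenin targets, and 2 each for nucleolar genes and ATF4 targets. Cholesterol synthesis, ER chaperones, glycolysis and DNA replication had 1 each, and mitochondrial mRNAs, hepatocyte proteins and histones had 0. EEF2, which translocates the ribosome, fell by 1.21 (SE 0.22) and RPLP0 by 1.11 (SE 0.23), at adjusted p = 0.016 and 0.020. Both calls ended without shCtrl input replicate 1 (adjusted p = 0.142 and 0.156), without input replicate 2 labelled shSETD2 (0.112 and 0.119) and without footprint replicate 1 of that label (0.0689 and 0.0761).

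With the label shMETTL14, efficiency fell for PNN, a nuclear speckle protein, by 3.28 (SE 0.28, adjusted p = 1.6e-05), with input at 206 against 78.7 CPM and footprints at 178 against 638 CPM in shCtrl. The splicing factor SRSF11 fell by 2.60 (SE 0.20, adjusted p = 6.5e-06), and MT-CO2 and MT-CO1, subunits of cytochrome c oxidase, by 2.63 (SE 0.35) and 2.35 (SE 0.33). GOLGA8A, GOLGA8B and NBPF20 also fell (-2.34, -2.42 and -2.47, SE 0.30, 0.33 and 0.30) but belong to near-identical families and are uncertain. Rises included MS4A15 (4.85, SE 0.57), KLK6 (3.41, SE 0.64), the neuronal secreted protein OLFM1 (3.36, SE 0.45) and the exchange factor IQSEC3 (2.95, SE 0.40). MS4A15 stood at 2.11 against 37.6 CPM in input and 13.8 against 8.06 CPM in footprints, so that its ratio moved mainly through input. Of 17122 genes, 687 rose and 959 fell. The split was 816 and 784 with genes above 1% of a library left out, 750 and 681 with the stricter filter, and 488 and 1353 with length and GC trends removed and the lysate as a block. Calls numbered 535 without shCtrl input replicate 1, 528 and 805 without input replicates 1 and 2 labelled shMETTL14, and 1083 without footprint replicate 2 of that label.

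The ratio of footprints to input fell for all 13 mitochondrially encoded mRNAs with the label shMETTL14 (13 adjusted over the list alone; median -1.30, camera adjusted p = 1.1e-16, adjusted p = 0.18 with an estimated correlation). The count was 5 without shCtrl input replicate 1 or input replicate 1 labelled shMETTL14, 8 without input replicate 2 or footprint replicate 1 of that label, and 7 without its footprint replicate 2, shCtrl footprint replicate 2 or either input labelled shSETD2. H3K36 enzymes and readers had 4 falls among 17 (5 adjusted over the list alone; median -0.43, adjusted p = 6.7e-04, adjusted p = 0.15 with an estimated correlation), and 2 without shCtrl input replicate 1; IWS1, a cofactor of SETD2 recruitment, fell by 1.45 (SE 0.26) and ZMYND11, a reader of H3K36me3, by 1.18 (SE 0.22). In m6A writers, erasers and readers, 4 of 21 fell (7 lower and 1 higher adjusted over the list alone; median -0.36, adjusted p = 6.7e-04, adjusted p = 0.18 with an estimated correlation), with the reader IGF2BP2 at -1.25 (SE 0.19). Nucleolar genes had 6 falls among 27 (7 adjusted over the list alone; median -0.28, adjusted p = 6.7e-04, adjusted p = 0.60 with an estimated correlation), with NOP56 at -2.07 (SE 0.22) and NOP58 at -1.65 (SE 0.20), and 3 without shCtrl input replicate 1 or input replicate 2 labelled shMETTL14. Camera also called translation factors (median -0.16, adjusted p = 0.016, adjusted p = 0.66 with an estimated correlation) and p53 targets (-0.31, adjusted p = 0.023, adjusted p = 0.60 with an estimated correlation). Positive medians were called for histones (0.33, adjusted p = 0.023, adjusted p = 0.66 with an estimated correlation) and markers of fibroblasts and stroma (0.78, adjusted p = 0.012, adjusted p = 0.18 with an estimated correlation). Ribosomal proteins were not called (median -0.02, 0.04 with genes above 1% of a library left out; adjusted p = 0.92), nor were ER chaperones, whose median and mean did not share a sign.

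Efficiency was higher with the label shSETD2 than with the label shMETTL14 for 851 genes and lower for 1244. The split was 1938 and 698 with scaling by library size alone. PNN (2.73, SE 0.28) and the splicing regulator SREK1 (2.77, SE 0.42) were higher. ZNF485 was lower (-3.52, SE 0.60), as were ACTG2 and the POTE genes POTEE, POTEI and POTEJ, which share actin sequence and are uncertain. Mitochondrial mRNAs had 6 of 13 higher (11 adjusted over the list alone; median 0.87, camera adjusted p = 1.9e-09, adjusted p = 0.81 with an estimated correlation), and 11 without either shCtrl footprint library. Ribosomal proteins had 20 of 78 lower and 2 higher (24 and 2 adjusted over the list alone; median -0.40, adjusted p = 2.6e-07, adjusted p = 0.81 with an estimated correlation). There the calls were 8 without input replicate 2 labelled shMETTL14, and 14 and 12 without input replicate 2 and footprint replicate 1 labelled shSETD2. Calls over all genes numbered 1364 and 785 without input replicates 1 and 2 labelled shMETTL14, 1242 and 972 without those labelled shSETD2, and 1211 without footprint replicate 1 of the latter label.

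**Figure D4:**
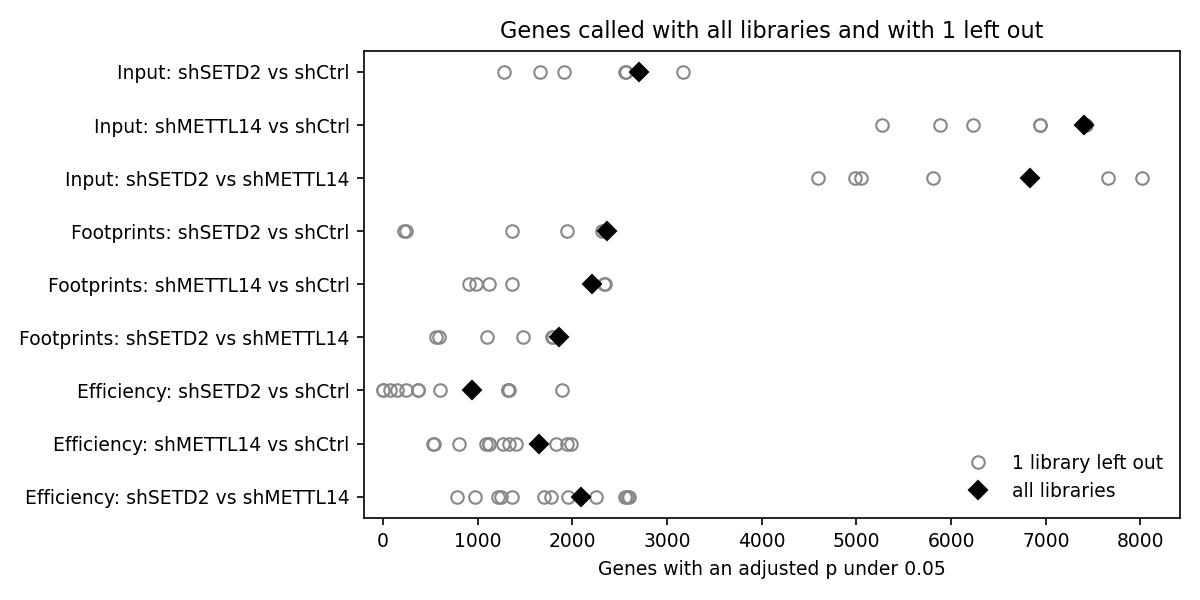
Number of genes with an adjusted p under 0.05 (x axis) in each of the 9 comparisons (y axis), with diamonds for all libraries and open circles for each fit with 1 library left out. Input calls for shMETTL14 against shCtrl ran from 5274 to 7426 around 7403, and efficiency calls for shSETD2 against shCtrl from 0 to 1892 around 935.

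The changes of both labels against the same shCtrl libraries were then set side by side. In input, 524 genes rose with both labels and 795 fell with both, against 258 and 297 for independent lists of those sizes and 0 in 50 simulated draws of unchanged groups; 456 moved in opposite directions. In footprints 163 rose and 511 fell with both (46.7 and 108 for independent lists, 0.12 and 0 simulated), and 21 moved oppositely. In efficiency 143 rose and 88 fell with both (15.6 and 30.6 for independent lists, 0.04 and 0.02 simulated), and 13 moved oppositely. The simulated counts leave out real effects and those for independent lists leave out the shared controls, so neither gives the overlap of unrelated changes. Across genes, which are not independent, the correlation of the log2 changes was 0.44 in input, 0.59 in footprints and 0.60 in efficiency, where shared controls alone gave 0.58, 0.50 and 0.53. With the stricter filter 161 genes rose and 334 fell with both in footprints, where the correlation was 0.49. In efficiency that correlation was 0.33, the same sign was seen for 56.4% of genes, and 105 genes rose and 32 fell with both, with no simulation run at that filter. The covariance was 0.12, 0.28 and 0.35 against a simulated 0.043, 0.072 and 0.10, differences of 0.076, 0.21 and 0.25. The same sign was seen for 64.1, 71.9 and 67.6% of genes against a simulated 68.8, 66.6 and 67.3%. The 2 shCtrl libraries per fraction were not split between the labels, so part of any excess may come from the shared controls.

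The authors' deposited table for shSETD2 lists 593 genes with higher and 836 with lower efficiency at their adjusted p under 0.05. In the authors' deposited table for shMETTL14 the numbers are 605 and 893. The sign of the log2 change was the same as in the edgeR interaction for 96.5% of 17122 genes for shSETD2 and 95.3% for shMETTL14. Both methods called 891 genes for shSETD2 and 1324 for shMETTL14, all with the same sign. The log2 changes of the 2 methods correlated at 0.9998 and 0.9997 across genes. Both form ratios from the same libraries, so shared signs give no independent support for the calls.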

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

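The tests of exchanged labels, hairpin reads, scaling and input bias were chosen only after the result was seen. The ratio with OR3A genes kept was added at the same stage. Values called a difference are shSETD2 minus shMETTL14 as labelled, and drew attention because the direct test between these labels passed its threshold, whereas the third pattern rests on both labels against shCtrl.

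The first pattern is that neither targeted gene was lower than in shCtrl where its shRNA is named, although in input SETD2 differed between the labels by -0.21 (adjusted p = 0.17), and by -0.71 (adjusted p = 1.5e-05) with scaling by library size alone. METTL14 differed by -1.38 in input and -1.69 in footprints, higher with its own label, and SETD2 by 1.72 in footprints, a call that ended with DESeq2 (adjusted p = 0.053) and without footprint replicate 2 labelled shMETTL14 (0.084) or replicate 2 labelled shSETD2 (0.81, adjusted p = 0.056). An exchange of the label shMETTL14 would leave METTL14 low in the input of another shRNA, but the 2 lowest shRNAs differed by 0.071 (SE 0.12). This argues against an exchange of that label with a METTL14 knockdown of at least 0.5 log2, while an exchange with a failed knockdown stays open. An exchange between shSETD2 and shCtrl would leave METTL14 unchanged, so this value cannot see it. SETD2 input stood at 27.2 CPM with the label shSETD2 and 24.3 CPM in shCtrl. Hairpin or vector reads counted as METTL14 could raise footprints above input; the interaction was 0.59 (SE 0.23, adjusted p = 0.108), past the threshold with the stricter filter (0.74, adjusted p = 0.031), without shCtrl footprint replicate 2 (0.89, adjusted p = 0.022) and with length and GC trends removed and the lysate as a block (0.74, adjusted p = 0.030). For SETD2 with the label shSETD2 the edgeR interaction was 1.42 (adjusted p = 0.063), with footprint replicates far apart at 91.9 and 252 CPM. Hairpin or vector reads and a higher METTL14 mRNA level cannot be told apart, because read positions and an expression construct were not examined here.

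The second pattern is the lower level of ribosomal protein mRNAs with the label shMETTL14, a difference of 1.44 in input (camera adjusted p = 0.25 with an estimated correlation) and 0.91 in footprints (adjusted p = 0.32 with an estimated correlation) between the labels. With length and GC trends removed the input median against shCtrl stayed at -1.02 (0.5 of the quartile range was 0.24), with 78 of 79 genes called. Over 3 other scalings the highest median was -0.95 (0.21), and in footprints it was -1.34 (0.33), which argues against scaling by abundant genes and against a bias of input alone as the whole cause. A biological difference between these stable lines may account for part of it, which is a hypothesis drawn from the same data and was not itself tested. RNA quality and a lower METTL14 dose were not tested, and the METTL14 level goes against the label.

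The third pattern is a set of genes more than 2-fold lower in the inputs labelled shSETD2 and shMETTL14 than in shCtrl input, 130 in all, of which 80 had no footprint call, among them MS4A15, SH3GL2, DMRT2, KLK6, INSL6, GNPTAB, UQCRC1 and MIGA1. Only 72 of the 80 were tested in footprints, so for the others, INSL6 among them, the lack of a call says nothing. Sharing of a common sequence could give such a set, but over all their transcripts 15.6% of 77 genes shared 25 bases with at least 3 others. In 100 sets matched on the summed length of transcripts the median was 28.6% and the 95th percentile 39.0%. Genomic DNA in the shCtrl inputs would raise olfactory receptor genes at least 2 times, but for the 371 outside the set the summed CPM in shCtrl was 0.857 (SE 0.143) of that with the label shMETTL14 and 1.05 (SE 0.141) of that with the label shSETD2, and with the 3 of the set kept (OR3A1, OR3A2, OR3A3) 1.09 (SE 0.270) and 1.31 (SE 0.291). Both inputs of shCtrl enter each value, so a property of these 2 libraries stays open beside a difference shared by the other lines.

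Mitochondrially encoded mRNAs differed by 0.95 in input (camera adjusted p = 0.46 with an estimated correlation) and 1.72 in footprints (adjusted p = 0.32 with an estimated correlation). Cholesterol synthesis and uptake differed by 0.92 in input (adjusted p = 0.25 with an estimated correlation) and 0.76 in footprints (adjusted p = 0.37 with an estimated correlation). The ATF4 list differed by 0.57 in input (adjusted p = 0.25 with an estimated correlation) and ER chaperones by 0.52 (adjusted p = 0.64 with an estimated correlation). Translation factors differed by 0.56 in input (adjusted p = 0.64 with an estimated correlation). Histones differed by 0.79 in input (adjusted p = 0.49 with an estimated correlation) and 0.83 in footprints (adjusted p = 0.37 with an estimated correlation). MYC differed by 1.09 in input (SE 0.11) and by -0.73 in efficiency (SE 0.18, adjusted p = 0.016), the latter past the threshold no longer with scaling by library size alone (0.058), with length and GC trends removed and the lysate as a block (0.084) or without input replicate 2 labelled shMETTL14 (0.099). SETD2 differed by 1.99 in efficiency (SE 0.43, adjusted p = 0.0068), and by 1.03 without footprint replicate 2 labelled shSETD2.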

How the results depend on the processing

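The removal of length and GC trends was an alternative chosen after seeing the data. Counts of calls stayed within 1.5 times in 84 of 90 fits with other settings and 42 of 72 with 1 library left out. These compare totals only, whatever the direction and identity of the genes. Direct input with scaling by library size alone stayed within that range, but shared 4618 of the 6837 main calls, and 1300 genes were higher and 8738 lower. The 72 include fits without a library of the shRNA not compared. Totals moved further in 9 of 12 fits for efficiency of shSETD2 and 0 of 6 for input of shMETTL14. Of 6687 fits of called named genes with other settings, 6326 kept direction and call, 353 fell short of the threshold and 8 reversed; with 1 library left out 4302 of 5292 kept both and 990 fell short. Of 258 fits of uncalled named genes, 6 passed the threshold and 5 reversed. A lone library left in a group is assumed to vary like the other groups. For efficiency, leaving out a library also changes the spread shared by input and footprints, so those counts do not measure dependence on that library alone. A count of 3 corresponds to 0.442 to 0.584 CPM in footprints and 0.173 to 0.319 CPM in input, below which a gene is not read.

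DESeq2 called 1738 genes in input for shSETD2 and put SETD2 footprints for shSETD2 at 1.53 (adjusted p = 0.084). Scaling by library size alone gave 3800 footprint calls for shMETTL14 and 422 efficiency calls for shSETD2. It shifted the median of all genes by 0.42 and -0.50 in input for shMETTL14 and for the direct comparison, 0.17, 0.37 and -0.20 in footprints for shSETD2, shMETTL14 and the direct comparison, and 0.24 in efficiency for shSETD2 and for the direct comparison. Under it METTL14 input for shSETD2 reversed to -0.012, CDT1 input for shMETTL14 to 0.077, SETD2 footprints for shMETTL14 to 0.21, and in direct input NSD1 to -0.025, BAX to -0.019, PHLDA3 to -0.19, IFI6 to -0.075 and CHEK2 to -0.054. Efficiency calls for shSETD2 were 443 with the stricter filter, 498 with the compared shRNAs alone and 1818 with length and GC trends removed and the lysate as a block. Removing those trends shifted the median of all genes by -0.13 and -0.12 in footprints and, with the lysate block as well, -0.15 and -0.13 in efficiency, and reversed MT-ATP8 input for shMETTL14 (0.14), SETD2 direct input (0.021, against -0.71 with scaling by library size alone) and IFI6 direct input (-0.13). With an estimated correlation camera called 0 of 225 lists (21 at an unadjusted p under 0.05), against 105. Without a filter the direction reversed for fatty acid synthesis in footprints of shMETTL14 (adjusted p = 0.949) and for liver transcription factors in direct footprints (0.858) and efficiency (0.840). It also ended 5 camera calls, of mitochondrial mRNAs (0.055) and fatty acid synthesis (0.072) in footprints and histones (0.074) in efficiency of shSETD2, DNA replication in footprints of shMETTL14 (0.050) and m6A writers, erasers and readers in direct efficiency (0.056), and added p53 targets in footprints of shMETTL14 (0.044). The stricter filter gave correlations between the labels of 0.33, 0.49 and 0.33 in input, footprints and efficiency, 334 shared footprint falls and 137 shared efficiency calls; an unadjusted p under 0.01 gave 484. The authors' table for shSETD2 held 2368 genes at adjusted p under 0.1 and 4321 at unadjusted p under 0.05, that for shMETTL14 4051 at the latter. The cause was not tested for any of these.

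With 1 library left out, calls ranged in input from 1281 to 3167 for shSETD2, 5274 to 7426 for shMETTL14 and 4597 to 8014 directly. Footprint calls ranged from 220 to 2349, 907 to 2349 and 561 to 1794, and efficiency calls from 0 to 1892, 528 to 1982 and 785 to 2602. The 0 stands for edgeR without shCtrl input replicate 1 or input replicate 2 labelled shSETD2, where 2848 and 3041 genes had an unadjusted p under 0.05 and DESeq2 over all libraries called 1248. SETD2 for shSETD2 ranged from 0.09 to 0.25 in input and 0.66 to 2.11 in footprints, and METTL14 for shMETTL14 from 1.37 to 1.62 and 1.88 to 2.33. METTL14 input for shSETD2 ranged from -0.0080 to 0.19, and SETD2 footprints for shMETTL14 from -0.46 to 0.10.

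Input and footprints, taken by replicate number to share a lysate, correlated at -0.03, 0.04 and 0.04 in their replicate differences over 13171 genes, for shCtrl, shMETTL14 and shSETD2. Between shRNAs, which share only a replicate number, the values for input ran from -0.35 to 0.10. With the lysate as a block, efficiency calls were 1121, 1597 and 2236, and with limma voom 939, 1700 and 2322.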

Other observations

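CEBPB, a liver transcription factor of the acute-phase response, fell with both labels, in input by 0.87 (SE 0.11) for shSETD2 and 1.23 (SE 0.11) for shMETTL14 and in footprints by 1.43 (SE 0.19) and 1.49 (SE 0.19). NR0B2, the nuclear receptor SHP that represses bile acid synthesis, rose with the label shMETTL14 in input (1.51, SE 0.12) and in footprints (1.30, SE 0.18), and lay lower with the label shSETD2 in the direct comparison of footprints (-1.19, SE 0.18). DKK1 and NKD1, both antagonists of Wnt signalling, fell with the label shMETTL14, in input by 1.72 (SE 0.11) and 1.07 (SE 0.11) and in footprints by 1.47 (SE 0.22) and 1.11 (SE 0.18).

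The plasma proteins SERPINC1 and APOH lay higher with the label shSETD2 than with the label shMETTL14, by 2.61 (SE 0.14) and 1.95 (SE 0.13) in input and 1.93 (SE 0.24) and 2.09 (SE 0.25) in footprints. The stress gene GADD45A, a p53 target, fell by 1.69 (SE 0.20) in footprints with the label shMETTL14. NKTR and BAZ2B, a bromodomain protein, were lower with the label shSETD2 than with the label shMETTL14 in input (-2.29 and -2.15, SE 0.14 each).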
